A study of Mus musculus with 8 samples.

How the data were processed

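The series holds RNA-seq of polyadenylated RNA from MLL-AF9 leukaemia cells sorted as GFP-positive, 7AAD-negative (living) cells from crushed bones of male recipient mice, after lysis of red cells, per the labels' protocols. The leukaemia cells had been given intravenously, without conditioning. Libraries were made with the Kapa mRNA HyperPrep kit and read as pairs of 38 bp, per the labels' protocols. One table covered the whole series and held raw counts per gene and library, deposited by the authors without normalization. Per the submitters' processing notes the genome build was mm10 and the tools included featureCounts and Cell Ranger, with no version or role. The aligner, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so counts of near-identical genes such as Hspa1a and Hspa1b or the ribosomal proteins with their processed pseudogenes, and of overlapping or antisense genes, are uncertain.

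The table had 27179 Entrez gene identifiers in 8 columns, each of which matched the description label of 1 sample. Groups came from the sample titles. Symbols and coordinates were taken from the RefSeq gene table of GRCm38.p6, the assembly that mm10 names, which matched 25275 identifiers. The other 1904 stayed in the tests under their number and held between 1.71% and 4.43% of a library's counts. The 13 mitochondrially encoded genes, and with them the planned mitochondrial share, were not analysed here. Library totals were between 14851240 and 38966911 counts. Within a group, the counts of every pair of libraries differed by far more than sampling noise (chi-square per degree of freedom 20.2 to 66.7), so no library was counted as a repeat of another. Same-numbered libraries of the groups were not taken as pairs.

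The main test was edgeR's quasi-likelihood F test with robust dispersion (edgeR 4.0.16 in R 4.3.3) on all 8 libraries, with TMM factors, edgeR's default filter on low counts (minimum count 10, minimum total 15), diet as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. It tested 13364 genes. Fold changes are BCAA-free against standard diet, the standard error is the log2 fold change divided by the square root of F, and CPM values use the TMM-scaled library sizes. Marker sums and Xist levels use CPM of the unscaled totals. The common biological coefficient of variation was 23.0%. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, for lists with at least 5 tested members, and adjusted over the 44 such lists. The 48 lists held 1069 entries for metabolism, stress, proliferation, immune signalling, the leukaemia programme, cell types and RNA quality. They were written before the data were examined, as were the groups, the tests, the named-gene rule and the alternatives, except those said to be added later. Library measures were compared by exact permutation over the 56 splits of 8 libraries into 5 and 3, two-sided, where the smallest p is 0.0357. With 14 such measures none could pass after adjustment unless several differed.

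The rule named the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between groups. It added up to 3 called members per list, the 2 members with the smallest p of each called list without called members, and 16 fixed genes of amino acid metabolism, stress, proliferation and leukaemia. This gave 65 genes, so some list members stand only in counts, and some genes that the rule named are not reported here. Further called members of short lists (such as Fdps and Bub1) were named after their values were seen. Of the genes named by the rule and not given elsewhere, Cd8a, Il7r, Hspa1a, Hspa1b, Jund, Fos, Ndufv1 and Ndufb8 did not pass in edgeR. DESeq2 called Cd8a (adjusted p = 0.00216), Il7r (0.00146), Hspa1a (0.0182) and Hspa1b (0.0132). In edgeR, Cd8a and Il7r passed without BCAA-free replicate 3 (0.016 and 0.00868), without that library and standard-diet replicate 1 (0.031 and 0.0341) and with GC and length trends removed (0.0452 and 0.0355), Cd8a and Hspa1a with no filter (0.00982 and 0.0198), and Hspa1b without BCAA-free replicate 1 (0.0209) and in the non-robust fit (0.0286).

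The procedure was tested on simulated counts drawn for the 13364 genes from the real means, library sizes and dispersions, with 200 genes changed. It recovered 27 of 67 genes changed 1.5-fold, 49 of 67 changed 2-fold and 51 of 66 changed 4-fold. Among genes with a mean of at least 10 CPM it recovered 27 of 45, 46 of 48 and 40 of 41. There were 13 false calls among 140, a larger share than the threshold of 0.05 aims at. In this 1 simulation the adjusted p was thus too lenient, which bears most on calls near the threshold. On the real counts, camera gave 5 of 100 random lists of 20 genes an unadjusted p under 0.05. Genes drawn at random need not vary together, so this does not test the preset correlation for lists whose genes do. Alternatives were other scalings (RLE and upper quartile), other filters, DESeq2 1.42.0, limma-voom with quality weights, a non-robust fit, a replicate block, leaving out each library, a fold threshold of 1.5, an adjusted p of 0.01, and for lists an estimated correlation, fry and ranks. Added after seeing the data were the removal of per-library trends with GC content and transcript length (splines with 5 degrees of freedom, a value being known for 94.3% of tested genes), the summed Y-linked CPM as a covariate, and leaving out both libraries that are deepest and richest in GC.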

Results

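RNA was profiled from mouse acute myeloid leukaemia cells driven by MLL-AF9, a fusion of the histone methyltransferase MLL with AF9 that arises from a chromosomal translocation. The cells carried green fluorescent protein (GFP), had been injected into male mice, and were sorted back out of the bone marrow as living GFP-positive cells. Recipients ate either a diet with the standard amino acids or one free of the branched-chain amino acids (BCAA) leucine, isoleucine and valine. The sample names say only BCAA, and the group is read as the BCAA-free diet from the title and design text of the series. All mice received 5+3 chemotherapy, which is cytarabine at 100 mg/kg daily for 5 days with doxorubicin at 3 mg/kg on the first 3 of those days. The deposited table held 5 libraries from the standard diet and 3 from the BCAA-free diet, and the labels call them biological replicates. Library totals ran from 16588662 to 38966911 counts on the standard diet and from 14851240 to 30306697 on the BCAA-free diet, and they did not differ in a two-sided exact permutation test (p = 0.857, the smallest possible value being 0.0357).

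The comparison asked how the leukaemia cells of mice on the BCAA-free diet differed, after chemotherapy, from those of mice on the standard diet. The clearest difference was a fall in the genes of cholesterol synthesis and uptake. Of 24 tested members of that list, 11 fell, none rose, and all 24 had a negative log2 fold change. Sqle, the squalene epoxidase of the sterol pathway, fell 2.35-fold, from 48.9 ± 6.28 normalised read counts scaled to library size (CPM; SD, n = 5) to 20.8 ± 4.98 CPM (SD, n = 3). Insig1, which holds the sterol-sensing complex in the endoplasmic reticulum, fell 2.18-fold, from 60.9 ± 9.32 to 28.0 ± 3.87 CPM. Msmo1, a sterol C4 demethylase, fell 2.12-fold, from 48.3 ± 4.71 to 22.8 ± 2.79 CPM. The log2 fold changes were -1.23 (SE 0.17), -1.12 (SE 0.15) and -1.08 (SE 0.14), each with an adjusted p of 0.00252 in edgeR's quasi-likelihood test. In the GRCm38 assembly Sqle (gene 20775) spans chromosome 15 from 59315092 to 59331193, Insig1 (231070) chromosome 5 from 28071412 to 28078662, and Msmo1 (66234) chromosome 8 from 64718123 to 64733578. The called members also included Fdps, Cyp51, Stard4, Idi1 and Fdft1, of which Idi1 passed in 1 of the 8 fits that each leave out 1 library, without standard-diet replicate 1, and Fdft1 in none.

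The list as a whole had a median log2 fold change of -0.52. It was called lower by camera, a competitive gene set test (adjusted p = 1.26e-29 over 44 lists), and it was the single list that kept its call when the correlation between genes was estimated from these libraries (adjusted p = 0.0192). Adjusted over the list alone, 14 members passed. Each of the 11 called genes was lower in all 3 BCAA-free libraries than in all 5 standard-diet libraries, a separation that nearly all called genes share. Sqle, Insig1, Msmo1, Cyp51, Fdps and Stard4 passed whichever single library was left out, and the count of called members was then between 7 and 9. It was 7 without standard-diet replicate 4, BCAA-free replicate 1 or BCAA-free replicate 2.

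**Figure D1:**
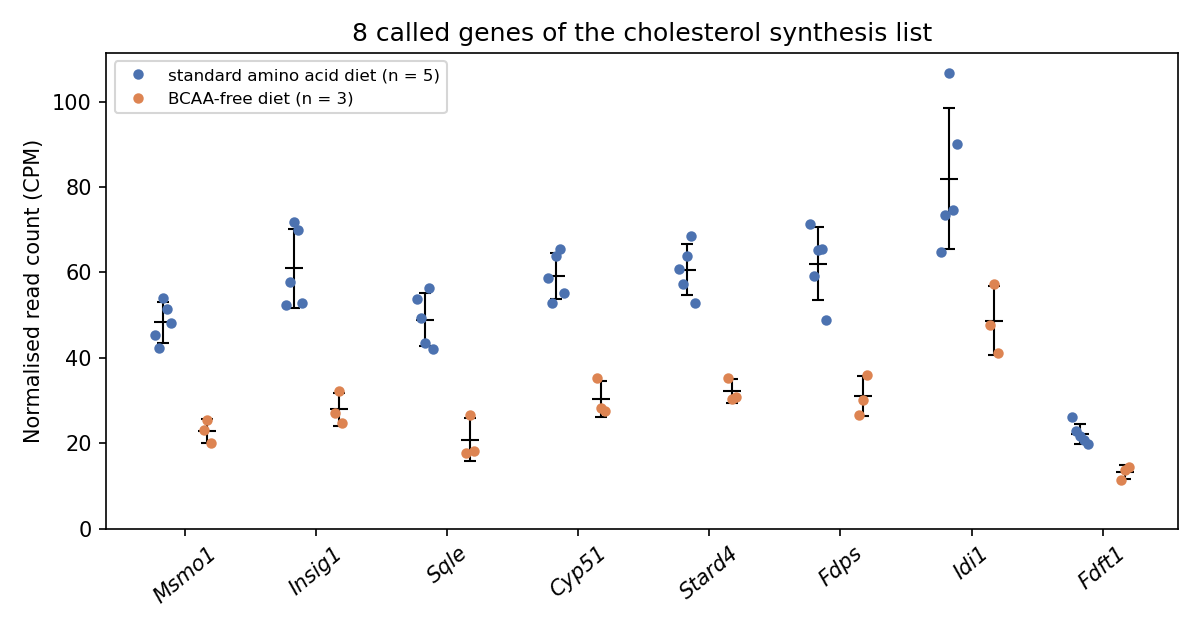
Normalised read counts (CPM, linear axis from 0) of 8 of the 11 cholesterol genes with an adjusted p under 0.05, in order of p. Points are libraries, 5 from the standard diet and 3 from the BCAA-free diet, and black bars give the mean ± SD of each group. For every gene shown the BCAA-free libraries lie below the standard-diet libraries, for example 20.8 against 48.9 CPM on average for Sqle.

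Of 13 tested members of the fatty acid synthesis list, 2 fell and none rose, and its desaturases went both ways. Scd2, a stearoyl-CoA desaturase, fell 2.05-fold, from 356 ± 48.6 to 174 ± 19.6 CPM (log2 fold change -1.04, SE 0.13, adjusted p = 0.00252). Fads1, the delta-5 desaturase, fell 1.97-fold, from 24.4 ± 2.83 to 12.4 ± 2.06 CPM (adjusted p = 0.0137), a call that was lost without BCAA-free replicate 1 (adjusted p = 0.0645). Camera called this list lower (median -0.13, mean 0.03, adjusted p = 0.0110), but not with an estimated correlation (adjusted p = 0.317) and not without BCAA-free replicate 3 (0.121), so that its mean differs in sign from its median and its test. In it, 3 members were lower and 1 higher when adjusted over the list alone. The higher one was the desaturase Scd1, chosen after its values were seen, at 21.9 ± 20.7 CPM on the BCAA-free diet and 4.45 ± 1.98 CPM on the standard diet, which did not pass over all genes (log2 fold change 2.30, adjusted p = 0.155). In the fatty acid oxidation list 1 of 21 tested members rose and none fell. This was Cpt1a, the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, which rose 1.55-fold, from 115 ± 7.44 to 179 ± 47.9 CPM (log2 fold change 0.64, SE 0.13, adjusted p = 0.0399). It passed in 2 of the 8 fits that each leave out 1 library, without standard-diet replicate 3 and without BCAA-free replicate 3, and its adjusted p reached 0.139 without BCAA-free replicate 1. That list was called higher (median 0.16, camera adjusted p = 0.000242) and lost the call with an estimated correlation (adjusted p = 0.235).

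Some genes of mitosis fell by a smaller amount. Of 26 tested members of the G2/M list, 6 fell (Top2a, Kif11, Hmmr, Nusap1, Bub1 and Anln), none rose, and 17 were lower when adjusted over the list alone. Top2a, the topoisomerase II isoform of dividing cells and a target of doxorubicin, fell 1.51-fold, from 1301 ± 55.4 to 860 ± 21.7 CPM (log2 fold change -0.60, SE 0.09, adjusted p = 0.00708). Kif11, the kinesin that separates spindle poles, fell 1.51-fold, from 421 ± 33.1 to 280 ± 21.5 CPM (adjusted p = 0.0135). Hmmr, a spindle-associated protein, fell 1.57-fold, from 188 ± 26.5 to 120 ± 7.38 CPM (adjusted p = 0.0182). Top2a and Kif11 lost their calls without BCAA-free replicate 2 (adjusted p = 0.0568 and 0.0988), and Hmmr without that library (0.0599), BCAA-free replicate 1 (0.0723) or standard-diet replicate 5 (0.0551). Nusap1 passed in 5 of the 8 fits that leave out 1 library, Anln in 4 and Bub1 in none. Mki67, a marker of cycling cells, was at 1749 ± 35.2 CPM on the BCAA-free diet and 2341 ± 130 CPM on the standard diet and did not pass in edgeR (adjusted p = 0.0531), although it did in DESeq2 (0.000213), in limma-voom (0.0326), with no filter on low counts (0.0385) and with trends of GC content and transcript length removed (0.0338). The G2/M list was called lower (median -0.36, camera adjusted p = 1.15e-17), and not with an estimated correlation (adjusted p = 0.131). No member was called without BCAA-free replicate 2, where 1523 of all tested genes had an unadjusted p under 0.05, and 2 were called without standard-diet replicate 5 and 2 without BCAA-free replicate 1. Over all 8 libraries DESeq2 called 9 members lower and limma-voom 6. The G1/S list, by contrast, had no called member among 25 by edgeR, DESeq2 or limma-voom, with 3 at an unadjusted p under 0.05. In the DNA repair list 1 of 21 tested members fell, Bard1, the partner of Brca1 (log2 fold change -0.56, SE 0.12, adjusted p = 0.0467), which passed in 1 of the 8 fits that leave out 1 library, without BCAA-free replicate 3, and reached 0.146 without BCAA-free replicate 2. Adjusted over the list alone, 6 were lower. That list was called lower (median -0.18, camera adjusted p = 1.26e-06) and not with an estimated correlation (adjusted p = 0.131).

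A few interferon-induced genes fell as well. Of 35 tested members of the type I interferon list, 4 fell (among them Ifit1, Dhx58 and Ifih1), none rose, and 15 were lower when adjusted over the list alone. Ifit1, which binds foreign RNA caps, had one of the largest falls, 4.62-fold, from 8.14 ± 2.38 to 1.79 ± 0.708 CPM (log2 fold change -2.21, SE 0.36, adjusted p = 0.00747). Ifih1, the double-stranded RNA sensor MDA5, fell 1.77-fold, from 92.1 ± 12.003 to 52.3 ± 15.8 CPM (adjusted p = 0.0415). Dhx58, a related RNA helicase, fell 2.21-fold, from 9.87 ± 1.89 to 4.46 ± 0.305 CPM (adjusted p = 0.0449). Camera called the type I list lower (median -0.42, adjusted p = 1.69e-12), and not with an estimated correlation (adjusted p = 0.131). Ifit1 alone of these passed whichever library was left out, and the count of called members was 1 without standard-diet replicate 2, 4 or 5 and 2 without BCAA-free replicate 3. Ifih1 passed in 3 of the 8 fits that leave out 1 library (adjusted p up to 0.153, without BCAA-free replicate 2) and Dhx58 in 1 (up to 0.107, without that library). The list of interferon-gamma and antigen presentation genes was called lower (median -0.45, camera adjusted p = 0.000108), but not with an estimated correlation (adjusted p = 0.517), and its members went both ways. Gbp3, a guanylate-binding protein, fell 1.90-fold, from 68.7 ± 14.2 to 36.1 ± 7.04 CPM (adjusted p = 0.0281). H2-Ab1, an MHC class II chain of antigen-presenting cells, rose 2.82-fold, from 5.07 ± 0.850 to 14.4 ± 9.18 CPM (adjusted p = 0.0475). Adjusted over the list alone, 10 members were lower and 4 higher. Without BCAA-free replicate 3 the list was not called (median -0.31, adjusted p = 0.190). Gbp3 passed in 3 of the 8 fits and H2-Ab1 in 1, that without BCAA-free replicate 3, and without BCAA-free replicate 2 they reached adjusted p of 0.132 and 0.306, with a log2 fold change of 0.87 for H2-Ab1 after 1.49 with all libraries.

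**Figure D2:**
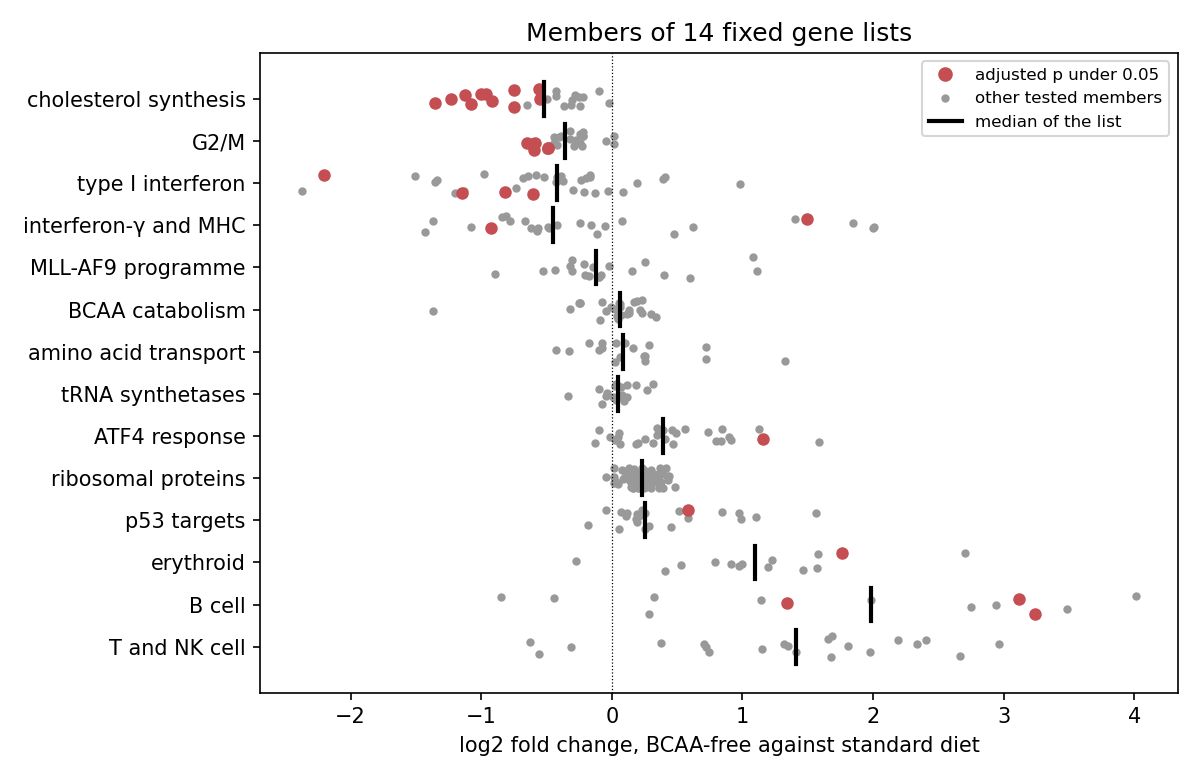
log2 fold change (BCAA-free against standard diet) of each tested member of 14 gene lists, 1 point per gene, with the median of each list as a black bar and genes with an adjusted p under 0.05 in red. The cholesterol list lies wholly below 0 (median -0.52), the BCAA catabolism list is centred near 0 (median 0.06) and the B cell list has the highest median (1.98). The vertical scatter within a list has no meaning.

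Genes that handle the branched-chain amino acids showed no called change. None of 26 tested members of the BCAA catabolism list passed in edgeR, DESeq2 or limma-voom, and 2 had an unadjusted p under 0.05. The median of that list was 0.06 and its mean -0.01 (camera adjusted p = 0.563), and none of its members passed when adjusted over the list alone. In each pair of values that follows, the BCAA-free diet comes first. Bcat2, the mitochondrial branched-chain aminotransferase, was at 71.9 ± 8.68 and 61.3 ± 6.72 CPM (log2 fold change 0.23, SE 0.12, adjusted p = 0.433). Bckdha, a subunit of the dehydrogenase that commits BCAA to oxidation, was at 42.7 ± 3.12 and 40.9 ± 10.2 CPM (adjusted p = 0.917). Bckdk, the kinase that inhibits that dehydrogenase, was at 66.7 ± 3.98 and 60.7 ± 9.26 CPM (adjusted p = 0.700). Bcat1, the cytosolic aminotransferase, was near the detection limit at 0.172 ± 0.110 and 0.475 ± 0.281 CPM (adjusted p = 0.599), with a count of 0 in standard-diet replicate 5. The leucine transporter Slc7a5 was at 122 ± 26.9 and 117 ± 15.1 CPM (adjusted p = 0.889), and its heavy chain Slc3a2 at 104 ± 28.4 and 87.4 ± 10.4 CPM (adjusted p = 0.503). None of 18 amino acid transport genes and none of 20 tRNA synthetases passed in edgeR, DESeq2 or limma-voom, each list having 3 genes at an unadjusted p under 0.05 (medians 0.08 and 0.05, camera adjusted p = 0.461 for both). Without BCAA-free replicate 2 the tRNA synthetase list was called higher (median 0.13, adjusted p = 0.0251). None of 34 genes of leucine sensing and mTORC1 passed in edgeR or limma-voom, against 1 in DESeq2 and 6 at an unadjusted p under 0.05 (median 0.06, camera adjusted p = 0.169). The mean log2 CPM of these genes was higher in all 3 BCAA-free libraries than in all 5 standard-diet libraries. The exact permutation p was 0.0357, the smallest possible, and 0.196 after adjustment over the lists. Other lists separated as fully, among them fatty acid oxidation, DNA repair, immediate early and monocyte. Of the leucine sensing members 20 had a positive and 14 a negative log2 fold change, with a mean of 0.19. The largest were Sesn3 (1.87, SE 0.73) and Castor1 (1.45, SE 0.65), both imprecise. None of the members of the amino acid transport, tRNA synthetase and leucine sensing lists passed when adjusted over the list alone.

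The list of genes induced by ATF4, the transcription factor of the amino acid starvation response, had 1 riser and no faller among 29 tested members. The riser was Phgdh, the first enzyme of serine synthesis, which rose 2.23-fold, from 17.03 ± 5.38 to 38.2 ± 6.05 CPM (log2 fold change 1.16, SE 0.23, adjusted p = 0.0281), and lost the call without standard-diet replicate 5 (adjusted p = 0.0728), BCAA-free replicate 1 (0.104) or BCAA-free replicate 2 (0.0878). Asns, asparagine synthetase and a standard readout of this response, was at 144 ± 40.2 CPM on the BCAA-free diet and 127 ± 30.2 CPM on the standard diet (adjusted p = 0.752). Ddit3 (adjusted p = 0.526), Chac1 (0.644), Trib3 (0.753) and Sesn2 (0.147) did not pass either. Adjusted over the list alone, 3 members were higher. Camera called the ATF4 list higher (median 0.39, adjusted p = 7.85e-05), but not with an estimated correlation (adjusted p = 0.521) and not without BCAA-free replicate 3 (median 0.13, adjusted p = 0.190). In the purine synthesis list 1 of 13 tested members rose. Impdh1, an inosine monophosphate dehydrogenase at the entry to guanine nucleotides, rose 2.95-fold, from 4.35 ± 0.823 to 12.9 ± 4.68 CPM (adjusted p = 0.00896), without a call for the list (camera adjusted p = 0.274) and without its own call when BCAA-free replicate 1 was left out (adjusted p = 0.0666).

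Ribosomal protein genes leaned upward in nearly all cases without any single call. Of 78 tested members, 77 had a positive log2 fold change, with a median of 0.23. None passed in edgeR, DESeq2 or limma-voom and 18 had an unadjusted p under 0.05. This list was called higher (camera adjusted p = 1.69e-12) and not with an estimated correlation (adjusted p = 0.517), and none of its members passed when adjusted over the list alone. Its median was 0.11 without BCAA-free replicate 3. The list of nuclear genes for oxidative phosphorylation had 57 of 70 positive values, none called in edgeR, DESeq2 or limma-voom and 11 at an unadjusted p under 0.05 (median 0.17, camera adjusted p = 3.78e-05, adjusted p = 0.714 with an estimated correlation and 0.0796 without BCAA-free replicate 3). The list of p53 targets had 1 riser among 23, Dglucy, a mitochondrial D-glutamate cyclase (log2 fold change 0.58, SE 0.12, adjusted p = 0.0401), which passed in 1 of the 8 fits that leave out 1 library, without standard-diet replicate 4, and reached 0.153 without BCAA-free replicate 2. Cdkn1a, the cell cycle inhibitor p21, was at 55.7 ± 6.93 CPM on the BCAA-free diet and 37.2 ± 16.4 CPM on the standard diet (adjusted p = 0.414), and passed only without standard-diet replicate 3 (0.0236). Adjusted over the list alone, 5 members were higher. Camera called the p53 list higher (median 0.25, adjusted p = 1.71e-05), and not with an estimated correlation (0.131). The immediate early list of serum-response genes was called higher too (median 0.67, adjusted p = 1.71e-05, 0.0746 with an estimated correlation), as was the heat shock list (median 0.27, 0.00356 and 0.521), the latter not without BCAA-free replicate 3 (0.205). No member of either passed in edgeR or limma-voom, 7 and 5 had an unadjusted p under 0.05, DESeq2 called 0 and 2 higher, and 2 and 3 were higher when adjusted over the list alone. Both lists had been set up to gauge the quality of the RNA. A technical difference between libraries and an effect of the diet cannot be told apart by them.

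The MLL-AF9 programme itself had no called gene among 20 by edgeR or limma-voom, while DESeq2 called 2 higher and 2 lower, 8 had an unadjusted p under 0.05, and 2 were higher and 3 lower when adjusted over the list alone (median -0.12, camera adjusted p = 0.233). Hoxa9, a homeobox gene switched on by the fusion, was at 165 ± 24.6 CPM on the BCAA-free diet and 175 ± 15.3 CPM on the standard diet (adjusted p = 0.806). Its partner Meis1 was at 120 ± 7.55 CPM on the BCAA-free diet and 128 ± 11.2 CPM on the standard diet (adjusted p = 0.735). The list of neutrophil primary granule genes was called lower (median -0.23, camera adjusted p = 0.00149), and not with an estimated correlation (adjusted p = 0.330). Its called member was Clec12a, a surface lectin of myeloid cells and no granule protein, which fell 1.87-fold, from 535 ± 88.0 to 286 ± 36.6 CPM (adjusted p = 0.00577). That call was lost without BCAA-free replicate 2 (adjusted p = 0.0515). Mpo, the myeloperoxidase of the granules, was at 6236 ± 635 CPM on the BCAA-free diet and 8798 ± 1044 CPM on the standard diet and did not pass in edgeR (adjusted p = 0.0605). It did pass in DESeq2 (0.00131), in limma-voom (0.0318), with no filter on low counts (0.0144), with trends of GC content and transcript length removed (0.0021), and without standard-diet replicate 3 (0.0405) or BCAA-free replicate 3 (0.0391). Siglecf, a sialic acid-binding lectin of eosinophils, fell 2.05-fold, from 70.5 ± 13.8 to 34.4 ± 3.71 CPM (adjusted p = 0.00535), the single called gene of 10 in the list of eosinophil, basophil and mast cell genes, which was not called (camera adjusted p = 0.814).

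Some markers of other marrow cells rose on the BCAA-free diet, at low levels and with much spread. Of 13 tested B cell markers, 3 rose, none fell, and 8 were higher when adjusted over the list alone. Cd79b, a chain of the B cell receptor complex, rose 2.54-fold, from 8.79 ± 1.71 to 22.4 ± 7.48 CPM (log2 fold change 1.34, SE 0.22, adjusted p = 0.00852). Cd79a, its partner, rose 8.68-fold, from 0.939 ± 0.549 to 8.39 ± 8.20 CPM (adjusted p = 0.0305). Outside the list, Spib, a transcription factor of B cells, rose 10.4-fold, from 0.748 ± 0.147 to 7.84 ± 8.97 CPM (adjusted p = 0.0182), and Tnfrsf13c, the receptor for the B cell survival factor BAFF, rose 18.7-fold, from 0.145 ± 0.121 to 2.89 ± 3.13 CPM (adjusted p = 0.0284). Camera called the B cell list higher (median 1.98, adjusted p = 1.40e-07) and not with an estimated correlation (adjusted p = 0.235). The calls of these single genes were lost without BCAA-free replicate 2, with adjusted p = 0.0764 for Cd79b, 0.235 for Cd79a, 0.276 for Spib and 0.291 for Tnfrsf13c. Without that library the log2 fold change was 1.95 for Cd79a (3.12 with all libraries), 1.83 for Spib (3.37) and 2.81 for Tnfrsf13c (4.22), while the list kept its camera call (median 1.15, adjusted p = 0.000132). In the fits without each other library Cd79b passed, while Cd79a and Spib each passed in 3 of the 8 fits and Tnfrsf13c in 4. In standard-diet libraries 8 of the B cell markers had a mean of at least 1 CPM.

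Of 21 tested T and NK cell markers none passed in edgeR or limma-voom, 9 had an unadjusted p under 0.05, DESeq2 called 3 higher, and 3 were higher and 1 lower when adjusted over the list alone. The T and NK cell list was called higher (median 1.41, camera adjusted p = 0.000105), but neither with an estimated correlation (adjusted p = 0.517) nor without BCAA-free replicate 2, where the median was 0.15 (adjusted p = 0.603). Single members rose in other lists of this kind. They were Cd163, a scavenger receptor of tissue macrophages (3.17-fold, adjusted p = 0.0450), Ctss, a lysosomal protease of monocytes and macrophages (2.04-fold, 0.0450), Car1, the carbonic anhydrase of red cell precursors (3.39-fold, 0.0210), and Cxcl12, a chemokine of marrow stroma (4.54-fold, 0.0374). They passed in 2, 1, 4 and 3 of the 8 fits that leave out 1 library, with adjusted p up to 0.195 for Cd163 and 0.13 for Ctss without BCAA-free replicate 2, 0.0844 for Car1 without BCAA-free replicate 3 and 0.119 for Cxcl12 without standard-diet replicate 4. Cd163 alone of the called risers had groups that overlapped. Camera called the tissue macrophage (median 0.93), monocyte (0.57), erythroid (1.10) and stroma (0.43) lists higher, with adjusted p of 1.73e-05, 0.0187, 2.03e-05 and 0.0481. With an estimated correlation the adjusted p was 0.295 for the first pair, 0.235 for the erythroid list and 0.536 for the stroma list. The monocyte call was lost without BCAA-free replicate 2 (0.135) or 3 (0.0584), and the stroma call without standard-diet replicate 2 (0.143) or BCAA-free replicate 1 (median -0.01, 0.592). Adjusted over the list alone, 8 macrophage members were higher and 1 lower, and the monocyte, erythroid and stroma lists had 1, 2 and 1 higher. Camera did not call the lists of mature neutrophils (adjusted p = 0.301), plasma cells (0.616) and dendritic cells (0.655), but it called the mature neutrophil list higher without standard-diet replicate 3 (median 0.75, adjusted p = 0.00172), without BCAA-free replicate 3 (0.71, 0.0416) and without both standard-diet replicate 1 and BCAA-free replicate 3 (0.69, 0.049). Two-sided exact permutation tests detected no difference in the summed CPM of a whole list for B cells (314 ± 128 on the BCAA-free diet, n = 3, and 204 ± 134 on the standard diet, n = 5, p = 0.357), T and NK cells (72.3 ± 48.3 and 46.9 ± 5.41, p = 0.5), erythroid cells (60.7 ± 31.9 and 27.8 ± 7.65, p = 0.0714) or macrophages, whose mean was lower on the BCAA-free diet (376 ± 61.6 and 419 ± 34.8, p = 0.321). So few libraries cannot show that there was none. The erythroid sums overlapped only narrowly, with a standard-diet maximum of 37.6 CPM and a BCAA-free minimum of 36.9 CPM. The summed CPM of 4 Y-linked genes was 21.7 ± 14.97 (SD, n = 3) on the BCAA-free diet and 10.0 ± 4.60 (SD, n = 5) on the standard diet. A two-sided exact permutation test detected no difference (p = 0.179), which with so few libraries does not show that there was none. All 4 genes had a positive log2 fold change (median 0.99), none passed over all genes, and 2 were higher when adjusted over the list alone. BCAA-free replicate 2 had the highest sum, 37.9 CPM. Xist, the RNA of the inactive X chromosome, was at 1506 to 1678 CPM on the BCAA-free diet and 1784 to 4162 CPM on the standard diet (exact permutation p = 0.0357, 0.5 after adjustment over 14 library measures).

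Across the 8 libraries the summed CPM of Y-linked genes was set against 5 marker sums on the log scale, with permutation tests. For the B cell sum Pearson's r was 0.792 (p = 0.02, adjusted 0.05) and Spearman's rho 0.69 (p = 0.0692, adjusted 0.191), with r 0.71 when the 2 libraries farthest from the median Y-linked sum were left out. For the T and NK cell sum r was 0.777 (p = 0.0191, adjusted 0.05) and rho 0.619 (p = 0.115, adjusted 0.191), with r 0.494 without those 2 libraries, on which this relation rests. Within the 5 standard-diet libraries r was 0.596 and 0.4, for which no test was run. The plasma cell sum (r 0.661, permutation p = 0.0743, adjusted 0.124), the macrophage sum (r 0.0246, p = 0.951) and the erythroid sum (r 0.0774, p = 0.857) did not pass.

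**Figure D3:**
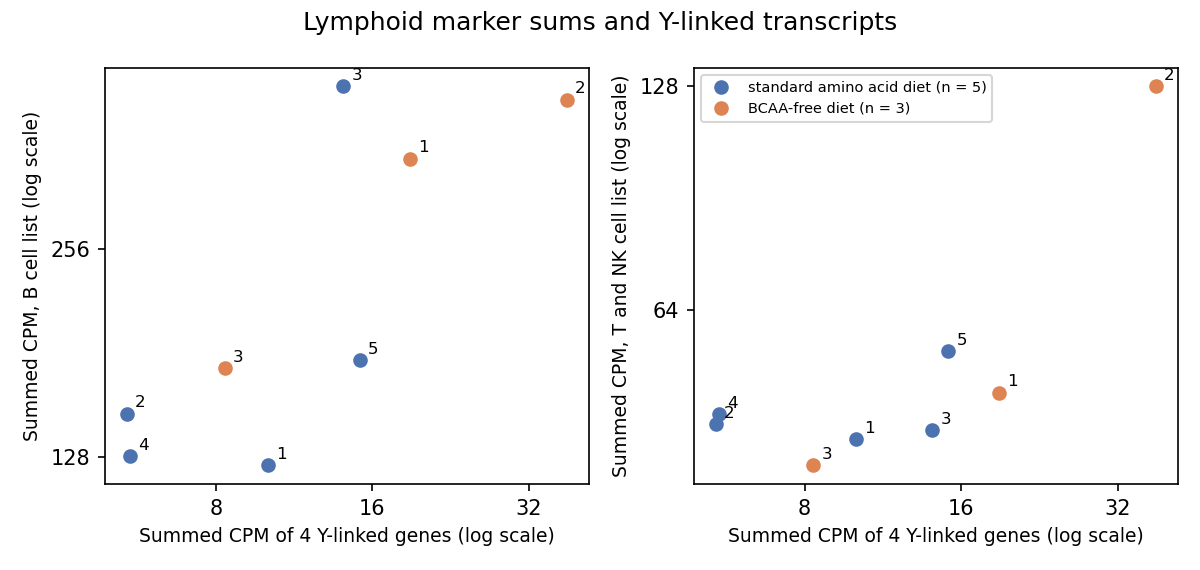
Summed CPM of the B cell list (left) and of the T and NK cell list (right) against the summed CPM of 4 Y-linked genes, on log axes, 1 point per library with its replicate number. BCAA-free replicate 2 has the highest Y-linked sum (37.9 CPM) and the highest T and NK cell sum (128 CPM), and standard-diet replicate 3 has the highest B cell sum (441 CPM).

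Across all 13364 tested genes, 101 passed an adjusted p of 0.05 in edgeR, 29 higher and 72 lower on the BCAA-free diet. In 28 of the 29 and in all 72 the groups did not overlap, as was so for 1182 of all tested genes (8.84%). A low p favours genes whose groups separate, so this adds no support to the calls. By lists, camera called 13 higher and 7 lower of 44 and left 24 uncalled, with adjusted p from 0.0896 to 0.973, while 4 lists had too few tested members. Of the uncalled lists not given elsewhere, those of ribosome biogenesis, MYC targets, glycolysis, NF-kB, the unfolded protein response and hypoxia were called in at least 1 fit that leaves out 1 library, with lowest adjusted p of 0.00249 and 0.00955 (both without BCAA-free replicate 2), 0.0352 (without standard-diet replicate 2), 0.0171 (without standard-diet replicate 3), 0.0225 (without BCAA-free replicate 3) and 0.0318 (without standard-diet replicate 5). With an estimated correlation the cholesterol list alone kept its call. The 10 largest rises with a mean of at least 1 CPM and no overlap included Tnfrsf13c, Spib, Cd79a, Calml4, Mfge8, Cxcl12, Thbs1, Ankrd13b and Ccl6. The 10 largest falls included Ifit1, Adgrv1, F630028O10Rik, Ano4, Sqle, Chst11, Dhx58, Insig1 and Msmo1. Calml4 rose 6.22-fold, Mfge8, which bridges dying cells to phagocytes, 5.96-fold, Thbs1, the matrix protein thrombospondin 1, 4.14-fold and the chemokine Ccl6 3.55-fold. Ankrd13b, an ankyrin repeat protein (gene 268445, chromosome 11 from 77470485 to 77490042), rose 3.89-fold, from 3.16 ± 1.08 to 12.3 ± 2.67 CPM (log2 fold change 1.96, SE 0.30, adjusted p = 0.00535). Chst11, a chondroitin sulfotransferase (gene 58250, chromosome 10 from 82984440 to 83195904), fell 2.24-fold, from 70.8 ± 3.92 to 31.8 ± 7.82 CPM (log2 fold change -1.16, SE 0.15, adjusted p = 0.00252). Adgrv1, an adhesion receptor, fell 3.25-fold, the channel protein Ano4 2.38-fold and the long noncoding RNA F630028O10Rik 2.56-fold.

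Of the 101 calls, 18 passed whichever library was left out. Leaving out BCAA-free replicate 2 kept 29 of the 101, the fewest of any library, and gave 3 higher and 29 lower genes in all. Counts without each of the other libraries ran from 11 to 78 higher and from 38 to 73 lower, the 78 arising without BCAA-free replicate 3. Among the named genes of the largest changes, Ankrd13b, Chst11, Sqle, Insig1, Msmo1 and Ifit1 passed in all 8 fits that leave out 1 library. Mfge8 passed in none of them, with 0.0504 as its lowest adjusted p, Calml4 in 1, Thbs1, Ccl6 and Ano4 in 2, and Adgrv1 and F630028O10Rik in 3. The highest adjusted p was 0.174 for Mfge8, 0.29 for Thbs1, 0.196 for Ccl6, 0.138 for Adgrv1 and 0.15 for F630028O10Rik, all without BCAA-free replicate 2 (where the log2 fold change of Thbs1 was 1.44 instead of 2.05), and 0.119 for Calml4 and 0.114 for Ano4, both without BCAA-free replicate 1.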

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

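The test with the Y-linked covariate, that of BCAA-free replicate 3 and that of the MLL-AF9 list were chosen after the result was seen. The removal of GC and length trends was added after the diet result but its predictions were written before its own outcome. The spread used to judge those removals (a bootstrap of the ratio to the uncorrected median) was chosen after a first outcome with the spread of the corrected median, and it changed the reading for B cell markers only, so both intervals are given. Neither interval is read as the spread between libraries. Of 79 values checked among the 5 standard-diet libraries, 6 had a library far from the other 4, where chance gives about 1 in 20. Standard-diet replicate 5 had 0 CPM of Bcat1, where the others had 0.48 to 0.738, and 0 CPM of Trib3, where the others had 0.567 to 1.38. The same library had 270.7 CPM of Scd2 against 365.1 to 388.5, and a T and NK cell sum of 56.36 CPM against 42.93 to 46.34. Standard-diet replicate 2 had 4162 CPM of Xist against 1784 to 2264. Standard-diet replicate 3 had a B cell sum of 441.1 CPM against 124.4 to 176.8, led by Ighm at 328.3 CPM and Igkc at 96.45 CPM.

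Camera called the lists of B cell and of T and NK cell markers higher on the BCAA-free diet, though not with an estimated correlation (adjusted p = 0.235 and 0.517) and with no T or NK marker passing alone in edgeR or limma-voom (9 at an unadjusted p under 0.05, 3 in DESeq2), in cells sorted for GFP, a gate that should remove cells of the recipient. Removing GC and length trends left the B cell median at 1.977 of 1.98 (interval 0.301 to 3.07, ratio 0.998, 0.896 to 1), which argues against those trends as the cause. Recipient cells may be the source of the T and NK cell signal, as recipients were male and Xist was high in every library. With the Y-linked sum as covariate the median was 0.06586 instead of 1.408 (interval -0.217 to 0.292). The signal rests on BCAA-free replicate 2, which had the highest Y-linked and the highest T and NK cell sum. Leaving out that library alone gave a median of 0.15. The covariate therefore cannot tell recipient cells from anything else particular to that library. For B cell markers the covariate gave 1.002, 0.506 of the uncorrected value (ratio -0.75 to 0.88), and 4 of 13 markers lay above all 5 standard-diet libraries in BCAA-free replicate 3, whose Y-linked sum was low, so recipient cells and a rise in the leukaemia cells cannot be told apart. The sex of the leukaemia donor is not given in the sources used here. Xist was at 1506 to 4162 CPM in every library, against a Y-linked sum of 5.39 to 37.9 CPM. Since recipients were male too, these values argue against a male donor. A diet effect on residual recipient cells stays open, untested.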

How the results depend on the processing

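The removal of GC and length trends, the Y-linked covariate and leaving out standard-diet replicate 1 with BCAA-free replicate 3 were added after seeing the data. Against 29 genes higher and 72 lower, no filter gave 69 and 168, DESeq2 122 and 254 (all 101 shared), limma-voom 17 and 48, and an adjusted p of 0.01 gave 5 and 22. A fold threshold of 1.5 in edgeR gave 0 and 0 (313 at an unadjusted p under 0.05), and a replicate block, which assumes a pairing the labels do not state, 0 and 0 (899 at an unadjusted p under 0.05). GC and length trends removed gave 43 and 159 (89 shared), the Y-linked covariate 10 and 64 (49 shared), and both libraries left out 45 and 51 (59 shared). Leaving out 1 library at a time gave 3 to 78 higher and 29 to 73 lower. The cause was not tested, except that the stricter thresholds pass fewer genes by construction. RLE (21 and 61), upper quartile (29 and 51), the strict filter (25 and 66) and the non-robust fit (25 and 52) stayed within 1.5 times, and no named gene or list reversed a call.

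Against 13 lists higher and 7 lower, an estimated correlation gave 0 and 1, and fry, which tests each list by itself, 2 and 4. Other settings gave 9 to 15 higher and 6 to 9 lower. Upper quartile scaling changed the sign of 4 uncalled list medians (lysosome, pyrimidine, G1/S, eosinophil) and RLE of 0. With GC and length trends removed 4 named genes lost their calls at log2 fold changes near those before, Clec12a (-0.76 after -0.90, adjusted p 0.097), H2-Ab1 (1.38 after 1.49, 0.0697), Cpt1a (0.57 after 0.64, 0.0558) and Cxcl12 (2.13 after 2.18, 0.0546). With the Y-linked covariate 5 lists lost theirs, fatty acid synthesis (0.0777), monocyte (0.225), macrophage (0.076), T and NK cell (0.518) and stroma (0.322), and 24 named genes lost theirs. These were every called B cell marker, among them Cd79b (0.0642) and Cd79a (0.201, log2 fold change 1.70 after 3.12), with Spib (0.265, 1.76 after 3.37), Tnfrsf13c (0.157, 2.80 after 4.22), H2-Ab1 (0.363, 0.77 after 1.49), Cpt1a (0.148), Phgdh (0.0956), Fads1 (0.0502), Bard1, Dglucy, Gbp3, Ifih1, Dhx58, Ctss, Cd163 (1.05 after 1.67), Cxcl12, Calml4, Mfge8, Thbs1, Ccl6 (0.98 after 1.83), Adgrv1, Ano4 and F630028O10Rik. Unlike those with smaller values, some of these genes kept log2 fold changes near those before. Examples are Fads1 (-0.97 after -0.98), Phgdh (1.07 after 1.16), Dglucy (0.62 after 0.58), Ano4 (-1.23 after -1.25) and F630028O10Rik (-1.33 after -1.35). For them the lost call does not mean that the covariate accounts for the difference. Named genes that lost their calls numbered 16 in limma-voom, 9 in the non-robust fit and 12 with both libraries left out, where Cd79a (3.97) and Tnfrsf13c (4.90) had larger log2 fold changes and passed. By the simulated data, depth and spread limit the detection of changes of 1.5-fold, of which 40.3% were recovered.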

Other observations

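The tests of the MLL-AF9 list, of glucocorticoid targets and with the Y-linked covariate were chosen after the result was seen. The splits and the removal of GC and length trends had predictions written before their outcome, and so had the LXR list. Among the genes that passed whichever library was left out, Dio2, Diaph3, Dach1, Ncam1 and Gria3 fell and Hif3a rose on the BCAA-free diet, outside the groups described so far and chosen after their values were seen.

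Hif3a (log2 fold change 1.37, SE 0.20, adjusted p = 0.00479) and Tsc22d3 (1.02, SE 0.21, 0.0418), both chosen after their values were seen, are induced by glucocorticoids, so exposure to these hormones may differ between the diets. Tsc22d3 lost its call without any 1 of the libraries except BCAA-free replicate 1. A list of 14 other targets, 3 of them also in fixed lists, had a median of 0.3 with 12 positive and was called higher by camera with the preset correlation (adjusted p = 0.0080451 over 46 lists). The prediction asked for no more than that call, but it was not kept with an estimated correlation (0.132), so the idea is left open.

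All 56 splits of the 8 libraries into 5 and 3 were fitted. The real split called 29 genes higher and 72 lower, the highest other split 13 and 6, so 1 of 56 splits reached each count. This argues against chance for the counts of genes, but 56 splits can give no smaller share, so chance is not excluded by it. As many lists were called higher in 6 of 56 splits (13, highest other 14) and lower in 25 of 56 (7, highest other 22), so chance is not excluded for the number of camera calls with the preset correlation.

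The fall of the cholesterol genes was set against technical and other sources. With GC and length trends removed the median was -0.5681 instead of -0.5235 (interval -0.824 to -0.37, ratio 1.09, 0.856 to 1.42), which argues against those trends. Dilution by recipient cells would lower leukaemia genes alike, but the MLL-AF9 median was -0.1191, and the lower end of its interval (-0.257 to 0.0654) lay narrowly short of 0.5 of the fall. With the Y-linked sum as covariate the cholesterol median was -0.43 (camera adjusted p = 1.97e-23) and 10 members were called lower. That sum measures recipient cells only if the leukaemia donor was female. The sex of the donor is not given, but Xist at 1506 to 4162 CPM in every library argues against a male donor. An excess of sterols may be a source, since LXR targets would then rise, but that list of 10 had a median of 0.3 and an adjusted p of 0.052926 over 46 lists (0.243 with an estimated correlation), which leaves it open. An effect of the diet on sterol-regulated genes stays a hypothesis, found and tested on the same data.

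For G2/M genes, with GC and length trends removed, the median was -0.3365 instead of -0.3556 (interval -0.41 to -0.281, ratio 0.946, 0.78 to 1.25), which argues against those trends. For ribosomal protein genes it was 0.163 instead of 0.231 (interval 0.115 to 0.201, ratio 0.706, 0.521 to 0.866), so these trends could account for part of that median, and it stays open. Leaving out 1 library at a time moved the uncorrected median between 0.107 and 0.291. That range is wider than the interval, which therefore does not hold the spread between libraries.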
